A study of Mus musculus with 16 samples.

How the data were processed

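The gene counts analysed here are the authors' deposited integer counts of uniquely aligned read pairs, 48709 genes by 16 libraries, with 0 blank gene names and 0 count columns that belong to no sample. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.20.0.422, trimmed with cutadapt 1.18 and Trimmomatic 0.38 and counted with featureCounts of Subread on build GRCm38.p6. The aligner, the strand setting and the annotation release are not given in the sources used here. GENCODE vM21 on GRCm38 gave gene names and coordinates here, and 122 symbols occur more than once. Raw reads were not used here. The authors' deposited LeafCutter tables hold an adjusted p-value per cluster and a usage fraction per intron and age, per the file headers. The authors' deposited DIEGO tables hold a p-value, a q-value and an abundance change score per junction, and the sign and the base of its logarithm are not given. Introns were taken as start plus 1 to end minus 1, and a change in usage as the later minus the earlier age. Library depth ran from 10.6 to 21.7 megacounts (M).

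SYN was compared with TH on 8 libraries, and the ages on the 12 SYN libraries. Sample groups, gene lists, tests and alternatives were fixed before the data were examined, apart from those named as later choices. Genes were filtered with filterByExpr by group, scaled by TMM and tested with edgeR 4.0.16 quasi-likelihood F tests with robust dispersions, under R 4.3.3. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes come from the fit. Log2 CPM had a prior count of 2. Each of 32 fixed gene lists, with at least 5 tested members, was tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Counts "adjusted over the list alone" apply the Benjamini-Hochberg method within the list. Adjusted p for lists are from camera and those for genes from edgeR, unless DESeq2 is named. CPM in the text come from each comparison's scaling, so 5 months SYN values differ between them. Figures and values per library use TMM over all 16 libraries, or total counts for sex genes. Python 3.11.15 with scipy 1.17.1, pandas 2.3.3 and numpy 2.4.6 did the splicing overlaps, with Fisher's exact test and Mantel-Haenszel odds ratios over 5 quintiles of expression.

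Genes were named by a fixed rule. The rule takes the 8 highest and 8 lowest log2 fold changes among called genes with a mean of at least 5 CPM, no overlap between groups and no predicted or pseudogene name. It adds up to 4 members of each list by adjusted p, or 2 uncalled members by p, the 8 splicing genes with the smallest adjusted p per table, 9 genes always shown, sex genes, and fixed splicing genes with a called cluster. The text gives a choice of these. Some genes that the rule names are not reported here.

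The alternatives were DESeq2 1.42.0 size factors, upper-quartile scaling, abundant classes removed, no filter, a filter of 1 CPM in 4 libraries, a replicate block, all 16 libraries in the fit, only the 8 libraries compared, each library left out, the DESeq2 Wald test, a fold of at least 2 and stricter thresholds for the splicing tables. Chosen after the data were seen were leaving out both libraries that stand apart, an exact test over the 4 pairs for the mitochondrial rRNA share, raising the smallest DIEGO p to the exact rank-sum p, the olfactory lists and the tests of technical explanations. Groups of libraries were also compared by exact permutation over 70 groupings.

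The 5 months SYN and TH columns carry the same 4 numbers and were taken as the same preparations, which is an inference. After group means were removed, replicates 1 and 4 correlated best with their own number (0.0884 and 0.144), while replicates 2 and 3 correlated better with each other's (0.0755 and 0.0231) than with their own (0.0200 and 0.0176). The age groups share replicate numbers alone and were not paired. In 3 simulations with 200 changed genes, the SYN against TH design recovered 19.7% of genes changed by 0.5 log2 units and 57.6% of those changed by 1, with a mean of 7 false calls. The age design recovered 28.6% and 68.2%, with 5 false calls. A list of 30 genes shifted by 0.5 was recovered in 3 of 3 simulations. No 2 libraries were copies of each other.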

Results

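RNA was measured in synaptosomes, a membrane fraction of pinched-off and resealed nerve terminals with attached postsynaptic membrane, prepared from the cerebral cortex of C57BL/6 mice. Synaptosome libraries (SYN) came from mice of 19 months, 5 months and 3 weeks, with 4 biological replicates per age. At 5 months, 4 libraries of total cortical homogenate (TH), the unfractionated starting material, served as the reference. Counts per gene were given for 48709 genes in all 16 libraries, and tables of splicing differences between ages were given for the synaptosomes. In megacounts (M), the 3 weeks SYN libraries held 17.7, 20.4, 21.7 and 16.9 M in replicates 1 to 4. The 5 months SYN libraries held 16.7, 15.3, 13.3 and 17.1 M. The 5 months TH libraries held 11.6, 17.5, 16 and 19.5 M, and the 19 months SYN libraries 15.5, 14.2, 10.9 and 10.6 M.

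The libraries differed in how much of their depth lay on the mitochondrial rRNAs, which the kit's depletion of cytosolic rRNA does not target. These took 39.3% ± 4.24 of the counts in 5 months SYN and 19.2% ± 1.91 in 5 months TH (mean ± SD, n = 4 each), 20.1 percentage points more in synaptosomes (two-sided exact permutation test, p = 0.0286, the smallest value that 4 against 4 libraries allow). With libraries of the same number taken as pairs, all 4 pairs differed in this direction, but an exact paired test, added after the data were seen, gave p = 0.125, the smallest value that 4 pairs allow. In 3 weeks SYN the share was 47.0% ± 4.00 and in 19 months SYN 37.9% ± 9.58. Between ages it did not differ past the threshold, with exact p = 0.0857 for 5 months against 3 weeks and exact p = 0.143 for 19 months against 3 weeks. The wide spread at 19 months came from replicate 1, with 52.3% against 32.9% to 33.6% in the other replicates. Outside the mitochondrial genome the libraries held 6.56 to 14.6 M counts. A count of at least 1 was found for 25300 ± 1442 genes in 5 months TH and 19380 ± 758 genes in 5 months SYN. The nuclear RNA Malat1 lay at 4817 CPM in 5 months SYN replicate 4 and at 947 to 1458 CPM in the other 5 months SYN libraries. The labels give no sex, and every library carried the Y-linked Ddx3y (17.25 to 63 CPM). Xist, the RNA of the inactive X chromosome, reached 5.92 CPM (92 counts) in 19 months SYN replicate 1 and less than 1 CPM in each of the others.

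**Figure D1:**
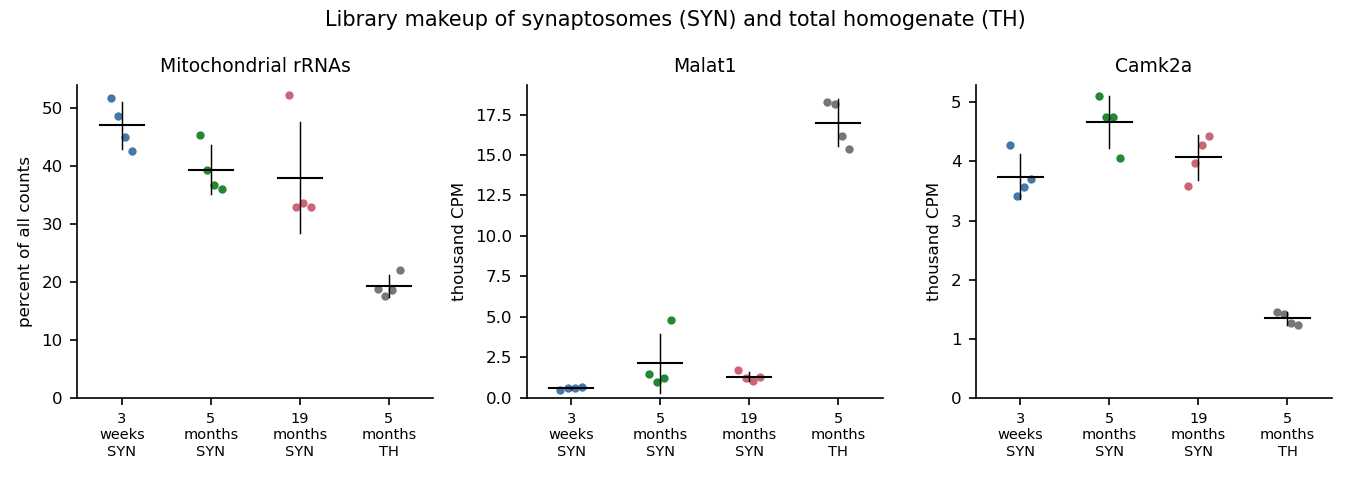
Each point is 1 library, grouped by age and fraction, with the group mean as a line and the SD as a bar (n = 4 per group). The panels give the percent of counts on the mitochondrial rRNAs and the levels of Malat1 and Camk2a in kilo-CPM, scaled over all 16 libraries. Malat1 was lower and Camk2a higher in 5 months SYN than in 5 months TH, and 5 months SYN replicate 4 had the highest Malat1 level of the 12 SYN libraries (4817 CPM).

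The comparison of SYN with TH at 5 months asks which cortical transcripts are relatively abundant in synaptosomes. Transcripts of the neuronal dendrite and synapse were higher in SYN, as were those of astrocytes, microglia and mitochondria, while transcripts of blood vessel cells and nuclear noncoding RNAs were lower. These are list calls of camera with its preset correlation, and none held with an estimated one (adjusted p = 0.251 for postsynaptic density, 0.207 for dendritic mRNAs, 0.0829 for astrocytes and for microglia, 0.227 for mitochondrial and for endothelial genes, 0.268 for nuclear RNAs). Kif5a, a kinesin motor of axonal and dendritic transport, stood at 10550 ± 674 CPM in SYN and 1959 ± 219 CPM in TH (log2 fold change 2.43, SE 0.0923, edgeR adjusted p = 3.26e-10). Camk2a, the calcium/calmodulin kinase of the postsynaptic density whose mRNA is carried into dendrites, stood at 5547 ± 496 against 1585 ± 134 CPM (log2 fold change 1.81, SE 0.0877, edgeR adjusted p = 1.16e-09). Malat1, a nuclear long noncoding RNA, stood at 2521 ± 2176 CPM in SYN and 20050 ± 1772 CPM in TH (log2 fold change -2.99, SE 0.595, edgeR adjusted p = 0.00623). Without 5 months SYN replicate 4 its log2 fold change was -3.82. Of 17374 genes tested, 4248 were higher and 4456 lower in SYN, together 50.1% of the genes.

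Among the highest were Rasl10b, a Ras-like GTPase (ENSMUSG00000020684, chromosome 11, 83409137 to 83421039), with 467 ± 56.8 against 72.8 ± 10.9 CPM (log2 fold change 2.68), and Dlgap3, a scaffold of the postsynaptic density (log2 fold change 2.34). Of 31 measured postsynaptic density genes, 26 were higher and 1 lower (26 and 1 adjusted over the list alone), with a median log2 fold change of 0.74 (camera adjusted p = 4.4e-10, adjusted p = 0.251 with an estimated correlation). They included the scaffolds Shank1 (2929 ± 329 against 616 ± 71.4 CPM, log2 fold change 2.25), Shank2 (1.99) and Dlg4 (707 against 312 CPM). Of 21 dendritic mRNAs, 19 were higher and 0 lower (19 and 0 adjusted over the list alone). The median was 1.23 (camera adjusted p = 1.86e-10, adjusted p = 0.207 with an estimated correlation). Adcy1, a calcium-stimulated adenylyl cyclase, was among them (log2 fold change 2.04). Of 30 glutamate receptor genes, 24 were higher and 2 lower (24 and 3 adjusted over the list alone). The median was 0.90 (camera adjusted p = 1.03e-07, adjusted p = 0.207 with an estimated correlation). The kainate receptor subunit Grik5 (1.71) and the NMDA receptor subunit Grin2a (1.26) led this group. Of 20 GABA and glycine receptor genes, 14 were higher and 1 lower (14 and 1 adjusted over the list alone). The median was 0.49 (camera adjusted p = 9.62e-05, adjusted p = 0.207 with an estimated correlation).

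Of 44 voltage-gated channel genes, 37 were higher and 3 lower (37 and 4 adjusted over the list alone), with a median log2 fold change of 0.81 (camera adjusted p = 9.7e-11, adjusted p = 0.207 with an estimated correlation). Hcn2, a hyperpolarization-activated cation channel, stood at 234 ± 21.4 against 59.9 ± 8.29 CPM and the sodium channel Scn8a at 1.44. Of 40 synaptic adhesion genes, 33 were higher and 0 lower (36 and 0 adjusted over the list alone). The median was 0.69 (camera adjusted p = 4.46e-11, adjusted p = 0.207 with an estimated correlation). Presynaptic vesicle and active zone genes were divided, with 19 of 33 higher and 4 lower (20 and 4 adjusted over the list alone), at a median of 0.50 (camera adjusted p = 0.000117, adjusted p = 0.278 with an estimated correlation). The active zone scaffolds Bsn (2.12) and Rims1 (1.36) were higher, and the SNARE protein gene Snap25 was lower (-0.29, edgeR adjusted p = 0.00357). Syn1, which coats synaptic vesicles, did not pass the test (246 ± 6.58 against 254 ± 14.6 CPM, log2 fold change -0.05, edgeR adjusted p = 0.606). Axon growth genes (18 of 32 higher, 1 lower, 18 and 1 adjusted over the list alone) had a median of 0.44 (camera adjusted p = 0.000204, adjusted p = 0.342 with an estimated correlation). Perineuronal net genes (7 of 10 higher, 0 lower, 7 and 0 adjusted over the list alone) had a median of 0.79 (camera adjusted p = 0.000839, adjusted p = 0.186 with an estimated correlation). Neuronal transcription factor genes had a median of 0.26 with 14 of 25 higher and 4 lower (14 and 4 adjusted over the list alone, camera adjusted p = 0.0175, adjusted p = 0.342 with an estimated correlation).

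Transcripts of glial cells were also higher in SYN. Of 24 astrocyte markers, 22 were higher and 0 lower (22 and 0 adjusted over the list alone), with a median log2 fold change of 1.04 (camera adjusted p = 1.33e-11, adjusted p = 0.0829 with an estimated correlation). Gfap, an intermediate filament of astrocytes, stood at 298 ± 7.04 against 73.4 ± 2.72 CPM (log2 fold change 2.02), and the calcium-binding S100b and the glycolytic Aldoc had log2 fold changes of 2.09 and 1.45. Of 24 microglial markers, 20 were higher and 0 lower (20 and 0 adjusted over the list alone). The median was 1.19 (camera adjusted p = 2.49e-09, adjusted p = 0.0829 with an estimated correlation). The integrin Itgam (1.95) and the protease Ctss (1.43) were among them. Oligodendrocyte precursor markers had a median of 0.66, with 11 of 16 higher and 0 lower (11 and 0 adjusted over the list alone, camera adjusted p = 0.000204, adjusted p = 0.0829 with an estimated correlation). For myelin genes the median was 0.38, with 16 of 29 higher and 1 lower (16 and 1 adjusted over the list alone, camera adjusted p = 0.000738, adjusted p = 0.342 with an estimated correlation), and Mbp, myelin basic protein, stood at 965 ± 117 against 535 ± 69.5 CPM. The complement gene C4b did not pass the test (log2 fold change 0.25, edgeR adjusted p = 0.0912), but did without 5 months SYN replicate 3 (0.32, edgeR adjusted p = 0.0459).

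All 13 mRNAs encoded by the mitochondrial genome were higher in SYN (13 and 0 adjusted over the list alone), with a median log2 fold change of 1.65 (camera adjusted p = 1.62e-07, adjusted p = 0.227 with an estimated correlation). They moved with the larger share of mitochondrial rRNA in these libraries. The cytochrome oxidase subunit mt-Co1 stood at 18900 ± 4056 against 6336 ± 628 CPM. The nuclear genes of oxidative phosphorylation had a median of 0.20, with 33 of 85 higher and 6 lower (33 and 6 adjusted over the list alone, camera adjusted p = 0.00599, adjusted p = 0.342 with an estimated correlation). Cytosolic ribosomal protein genes had a median of 0.47, with 35 of 82 higher and 3 lower (35 and 3 adjusted over the list alone, camera adjusted p = 4.22e-05, adjusted p = 0.207 with an estimated correlation). Rps15 (2.07) and Rpsa (59.3 ± 9.58 against 15.3 ± 2.96 CPM) were the leading members, and like other ribosomal protein genes they share sequence with pseudogene copies, so their counts are uncertain. Cholesterol biosynthesis genes had 12 of 24 higher and 1 lower (12 and 1 adjusted over the list alone) at a median of 0.17 (camera adjusted p = 0.0441, adjusted p = 0.401 with an estimated correlation). The call of cholesterol biosynthesis was lost with a replicate block (adjusted p = 0.0519), DESeq2 size factors (0.0515) or abundant classes removed (0.0514). It was also lost without 5 months SYN replicate 1 (0.0522), and without 5 months TH replicate 1 (0.0625) or replicate 4 (0.058).

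Endothelial and mural cell markers were lower in SYN, with 22 of 25 lower and 0 higher (23 and 0 adjusted over the list alone) and a median log2 fold change of -2.36 (camera adjusted p = 1.62e-07, adjusted p = 0.227 with an estimated correlation). The adhesion molecule Pecam1 stood at 1.34 ± 0.598 against 13.3 ± 2.72 CPM (log2 fold change -3.29) and the transporter Slco1a4 at 2.58 ± 0.928 against 25.1 ± 2.30 CPM (-3.25). The vascular receptors Tek (-3.56) and Ptprb (-3.44) reached -5.27 and -4.53 without 5 months SYN replicate 4, in which Ptprb was highest of the 5 months SYN libraries. Collagens and basement membrane genes had a median of -0.80, with 17 of 27 lower and 2 higher (17 and 2 adjusted over the list alone, camera adjusted p = 0.00423, adjusted p = 0.207 with an estimated correlation). Nuclear long noncoding RNAs had a median of -2.45, with 10 of 13 lower and 3 higher (10 and 3 adjusted over the list alone, camera adjusted p = 0.00537, adjusted p = 0.268 with an estimated correlation). Kcnq1ot1, an imprinted antisense RNA, was at -3.37, or -4.70 without 5 months SYN replicate 4, and Snhg14 at -1.33. Small nucleolar RNA genes had a median of -2.17, with 9 of 16 lower and 0 higher (11 and 0 adjusted over the list alone, camera adjusted p = 0.000738, adjusted p = 0.329 with an estimated correlation), and Scarna13, a Cajal body RNA, was at -3.45. Splicing factor genes had a median of -0.50, with 39 of 60 lower and 7 higher (40 and 7 adjusted over the list alone, camera adjusted p = 6.52e-05, adjusted p = 0.235 with an estimated correlation). Srsf5 (-1.52) and Hnrnpl (-1.17) were lower, while Celf4, a neuronal RNA-binding protein, was higher (0.99).

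In this comparison 18 lists were higher and 5 lower by camera with its preset correlation, and 9 were not called. With an estimated correlation 0 were higher and 0 lower. The uncalled meninges list was lower without 5 months TH replicate 2 (-1.07, adjusted p = 0.0308), with adjusted p up to 0.792 without another library. Among the uncalled lists, cell cycle genes had a median of -0.04 and a mean of -0.11 with an upward test direction, and immune genes a median of -0.02 and a mean of 0.08 with an upward direction. With upper-quartile scaling the genes higher and lower numbered 3367 and 5525, so that 37.9% of the called genes were higher in place of 48.8%, and the median of all genes shifted by -0.14 on the log2 scale.

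**Figure D2:**
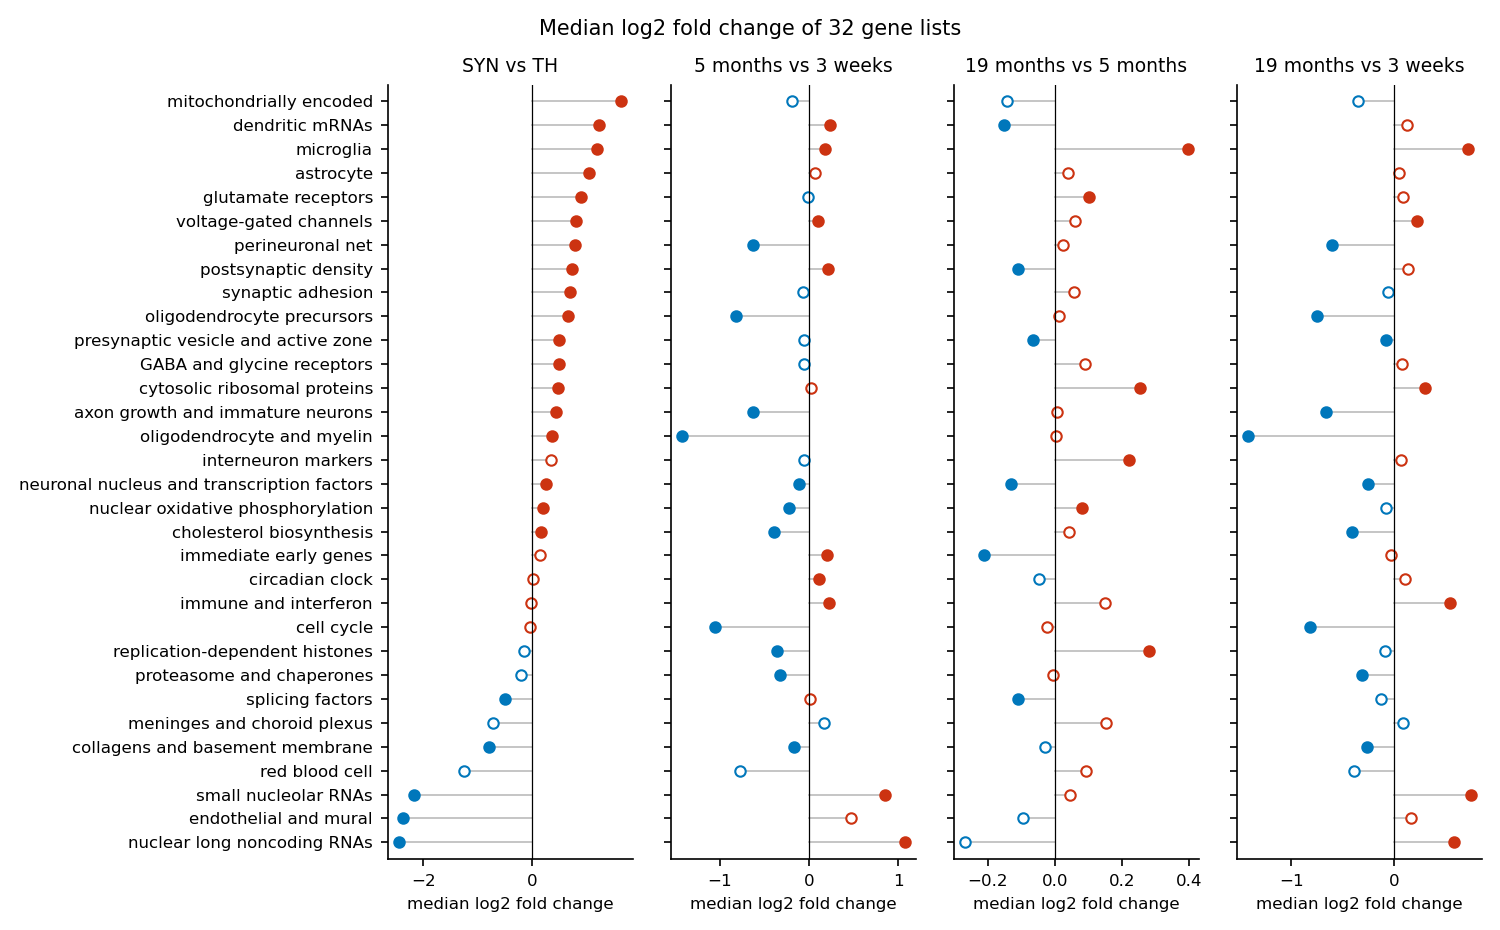
Median log2 fold change of each of the 32 gene lists in the 4 comparisons, each panel with its own horizontal scale. Red marks an upward and blue a downward direction of the camera test, and filled points an adjusted p under 0.05 with the preset correlation. Endothelial and mural markers (-2.36) and nuclear long noncoding RNAs (-2.45) lie lowest in SYN against TH, and myelin genes lie lowest in both comparisons with 3 weeks (-1.43 at 5 months, -1.42 at 19 months).

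Synaptosomes of 5 months and 3 weeks were compared to find transcripts that differ between the juvenile and the adult synaptosome fraction. Transcripts of myelin, of oligodendrocyte precursors, of growing axons and of dividing cells were lower at 5 months as lists, and the complement gene C4b was higher. With an estimated correlation the oligodendrocyte precursor call held (adjusted p = 0.0317), and those of myelin (adjusted p = 0.399), axon growth (0.0585) and cell cycle genes (0.0585) did not. Cnp, an enzyme of the myelin sheath (ENSMUSG00000006782, chromosome 11, 100574904 to 100591729), stood at 54.9 ± 7.03 CPM at 5 months and 263 ± 39.3 CPM at 3 weeks (log2 fold change -2.26, SE 0.114, edgeR adjusted p = 5.74e-14). Gpr17, a receptor of differentiating oligodendrocytes, stood at 26.0 ± 2.51 against 122 ± 17.1 CPM (log2 fold change -2.23, SE 0.111, edgeR adjusted p = 4.91e-14). C4b, complement component 4B, stood at 20.8 ± 2.46 against 6.26 ± 0.926 CPM (log2 fold change 1.74, SE 0.150, edgeR adjusted p = 2.28e-09). Of 15344 genes tested, 2035 were higher and 1738 lower at 5 months, together 24.6% of the genes.

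Of 29 myelin genes, 17 fell and 3 rose (17 and 3 adjusted over the list alone), with a median log2 fold change of -1.43 (camera adjusted p = 4.95e-08, adjusted p = 0.399 with an estimated correlation). The tight junction gene Cldn11 (-2.98), Mog (-2.66) and Mbp (702 ± 85.1 against 2286 ± 408 CPM, -1.70) were among those that fell. Of 16 oligodendrocyte precursor markers, 13 fell and 0 rose (13 and 0 adjusted over the list alone). The median was -0.82 (camera adjusted p = 1.54e-08, and adjusted p = 0.0317 with an estimated correlation). Enpp6, an enzyme of newly forming oligodendrocytes, was at -2.93 and the transcription factor Olig1 at -1.35. Of 34 genes of axon growth and immature neurons, 24 fell and 0 rose (25 and 0 adjusted over the list alone). The median was -0.63 (camera adjusted p = 1.59e-11, adjusted p = 0.0585 with an estimated correlation). The actin regulator Marcksl1 stood at 21.9 ± 3.37 against 109 ± 20.5 CPM (-2.31), and the guidance molecule Sema6a (-1.43) and the tubulin Tuba1a (-1.28) also fell. Of 20 cell cycle genes, 8 fell and 0 rose (11 and 0 adjusted over the list alone). The median was -1.06 (camera adjusted p = 3.09e-06, adjusted p = 0.0585 with an estimated correlation). The proliferation marker Mki67 (-3.02) and the topoisomerase Top2a (-2.82) led this list.

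The matrix genes Col1a1 (6.06 ± 2.22 against 59.1 ± 16.4 CPM, -3.29) and Col3a1 (-2.76), both markers of the meninges list, fell. Collagens and basement membrane genes had a median log2 fold change of -0.17, with 6 of 26 lower and 0 higher (6 and 0 adjusted over the list alone, camera adjusted p = 0.0316, adjusted p = 0.454 with an estimated correlation). Without 3 weeks SYN replicate 4 (-0.21, adjusted p = 0.0697) or 5 months SYN replicate 1 (-0.07, adjusted p = 0.0705) this list was not called, and its median was -0.29 without 5 months SYN replicate 3 and -0.30 without replicate 4. Perineuronal net genes had a median of -0.63, with 6 of 10 lower and 1 higher (7 and 1 adjusted over the list alone, camera adjusted p = 0.000424, adjusted p = 0.2 with an estimated correlation), among them tenascin C (Tnc, -1.63) and the link protein gene Hapln1 (-1.28). Cholesterol synthesis genes had a median of -0.40, with 10 of 24 lower and 0 higher (10 and 0 adjusted over the list alone, camera adjusted p = 0.000219, adjusted p = 0.399 with an estimated correlation). Hmgcs1, an enzyme of the pathway, had a log2 fold change of -1.17. Proteasome and chaperone genes had a median of -0.33, with 12 of 32 lower and 1 higher (15 and 1 adjusted over the list alone, camera adjusted p = 0.000424, adjusted p = 0.161 with an estimated correlation). Nuclear genes of oxidative phosphorylation had a median of -0.22, with 23 of 85 lower and 6 higher (24 and 6 adjusted over the list alone, camera adjusted p = 0.00903, adjusted p = 0.53 with an estimated correlation). Replication-dependent histone genes had a median of -0.36, with 8 of 32 lower and 2 higher (8 and 2 adjusted over the list alone, camera adjusted p = 0.0126, adjusted p = 0.152 with an estimated correlation). Neuronal transcription factor genes had a median of -0.11, with 6 of 25 lower and 0 higher (8 and 0 adjusted over the list alone, camera adjusted p = 0.0343, adjusted p = 0.53 with an estimated correlation). That call was lost without 3 weeks SYN replicate 1 (-0.07, adjusted p = 0.143), 5 months SYN replicate 2 (-0.13, adjusted p = 0.0659) or 5 months SYN replicate 4 (-0.09, adjusted p = 0.0727). The median was -0.19, -0.18 and -0.20 without 3 weeks SYN replicate 2, its replicate 4 and 5 months SYN replicate 1.

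Synaptic transcripts changed in both directions. Of 31 postsynaptic density genes, 14 rose and 5 fell (15 and 6 adjusted over the list alone), with a median log2 fold change of 0.21 (camera adjusted p = 0.0126, adjusted p = 0.581 with an estimated correlation). Shank1 stood at 2129 ± 241 against 1250 ± 16.4 CPM (0.77) and the spine protein gene Ppp1r9b at 0.91, while Nrgn, a calmodulin-binding postsynaptic protein, stood at 260 ± 19.6 against 506 ± 39.9 CPM (-0.96). Of 21 dendritic mRNAs, 10 rose and 3 fell (11 and 3 adjusted over the list alone). The median was 0.23 (camera adjusted p = 0.0234, adjusted p = 0.53 with an estimated correlation). The list was not called without 5 months SYN replicate 1 (adjusted p = 0.0509). Itpr1, the calcium release channel, was at 1.19 and Camk2a at 0.34 (edgeR adjusted p = 0.0146). Camk2a lost its call without 3 weeks SYN replicate 3 (edgeR adjusted p = 0.0579) or 5 months SYN replicate 1 (0.0523). Of 44 voltage-gated channel genes, 12 rose and 3 fell (13 and 3 adjusted over the list alone). The median was 0.10 (camera adjusted p = 0.0305, adjusted p = 0.784 with an estimated correlation), Hcn2 (0.76) and the potassium channel Kcna2 (0.50) among them. Without 3 weeks SYN replicate 1 (0.04, adjusted p = 0.312), 5 months SYN replicate 2 (adjusted p = 0.115) or 5 months SYN replicate 3 (adjusted p = 0.0785) the channels were not called, and their median was 0.16 without 3 weeks SYN replicate 4 or 5 months SYN replicate 4. Presynaptic genes as a list were not called (median -0.05, 6 higher and 10 lower, 8 and 12 adjusted over the list alone, camera adjusted p = 0.247), with Syn1 at -0.59 and Snap25 at 0.30. Dlg4 did not pass the test (514 ± 34.2 against 520 ± 50.8 CPM, log2 fold change -0.02, edgeR adjusted p = 0.911).

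Of 27 immune genes, 7 rose and 0 fell (7 and 0 adjusted over the list alone), with a median log2 fold change of 0.23 (camera adjusted p = 0.0178, adjusted p = 0.355 with an estimated correlation). The lysozyme gene Lyz2 (1.66) and C4b led this list, which was not called without 5 months SYN replicate 1 (0.10, adjusted p = 0.0856) and had a median of 0.35 without its replicate 3. Of 24 microglial markers, 7 rose and 0 fell (7 and 0 adjusted over the list alone). The median was 0.18 (camera adjusted p = 0.0198, adjusted p = 0.581 with an estimated correlation). Ctss stood at 48.9 ± 6.02 against 27.6 ± 3.58 CPM (0.82), and the list was not called without 3 weeks SYN replicate 1 (0.13, adjusted p = 0.138). The microglial median was 0.31 without 3 weeks SYN replicate 2 and 0.28 without 5 months SYN replicate 4. Immediate early genes had a median of 0.20, with 10 of 27 higher and 2 lower (11 and 2 adjusted over the list alone, camera adjusted p = 0.0126, adjusted p = 0.53 with an estimated correlation), among them Fosb (1.28) and Nr4a3 (0.81). Its median was 0.11 without 3 weeks SYN replicate 3 and 0.33 without 3 weeks SYN replicate 4. Circadian clock genes had a median of 0.11, with 4 of 17 higher and 0 lower (5 and 0 adjusted over the list alone, camera adjusted p = 0.0247, adjusted p = 0.53 with an estimated correlation), a call lost without 3 weeks SYN replicate 4 (adjusted p = 0.064) or 5 months SYN replicate 1 (0.0735), with a median of 0.17 without 3 weeks SYN replicate 1. Astrocyte markers were not called (4 higher and 4 lower, 4 and 4 adjusted over the list alone, camera adjusted p = 0.62), and Gfap was at 0.21 (edgeR adjusted p = 0.0754), or 0.26 with edgeR adjusted p = 0.0215 without 3 weeks SYN replicate 1.

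Nuclear long noncoding RNAs had a median log2 fold change of 1.07, with 7 of 13 higher and 1 lower (8 and 1 adjusted over the list alone, camera adjusted p = 0.00953, adjusted p = 0.434 with an estimated correlation). Malat1, Meg3 and Mir124a-1hg were highest in 5 months SYN replicate 4 among the SYN libraries, and without it the median was 0.51, Meg3 was at 1.59 in place of 2.27, Malat1 at 1.09 in place of 1.90 and Mir124a-1hg at 1.80 in place of 2.40. Malat1 stood at 1830 ± 1575 against 491 ± 61.5 CPM (edgeR adjusted p = 0.0193) and lost its call without 3 weeks SYN replicate 2 (0.0538) or replicate 3 (0.0564). Small nucleolar RNA genes had a median of 0.85, with 4 of 8 higher and 0 lower (4 and 0 adjusted over the list alone, camera adjusted p = 0.0206, adjusted p = 0.53 with an estimated correlation), or 1.40 without 3 weeks SYN replicate 4. Without both libraries that stand apart, 5 months SYN replicate 4 and 19 months SYN replicate 1, this call was lost (adjusted p = 0.0548). S100a5, a calcium-binding protein of olfactory sensory neurons, rose (log2 fold change 3.70, 9.75 ± 6.28 against 0.744 ± 0.290 CPM, edgeR adjusted p = 0.00309). The mRNA mt-Co1 did not pass the test (-0.19, edgeR adjusted p = 0.715).

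In all, 9 lists were higher and 11 lower at 5 months than at 3 weeks, and only the oligodendrocyte precursor call held with an estimated correlation. Synaptic adhesion genes, not called with all libraries (-0.07, adjusted p = 0.116), were lower without 3 weeks SYN replicate 1 (-0.16, adjusted p = 0.000948) or 5 months SYN replicate 2 (0.0376) or 3 (0.0401). Endothelial markers (0.47, adjusted p = 0.0645) were higher without 3 weeks SYN replicate 3 (0.043) or 5 months SYN replicate 2 (0.0217) or 3 (0.0401), and red blood cell genes lower without 3 weeks SYN replicate 1 (-1.02, adjusted p = 0.0297) or 5 months SYN replicate 4 (0.0487). With 1 library left out the medians of these 3 lists also came as near to 0 as -0.03, 0.15 and -0.53, and their largest adjusted p were 0.588, 0.261 and 0.403. The meninges list, which was not called, had a median of 0.16 and a mean of -0.22 with a downward test direction.

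**Figure D3:**
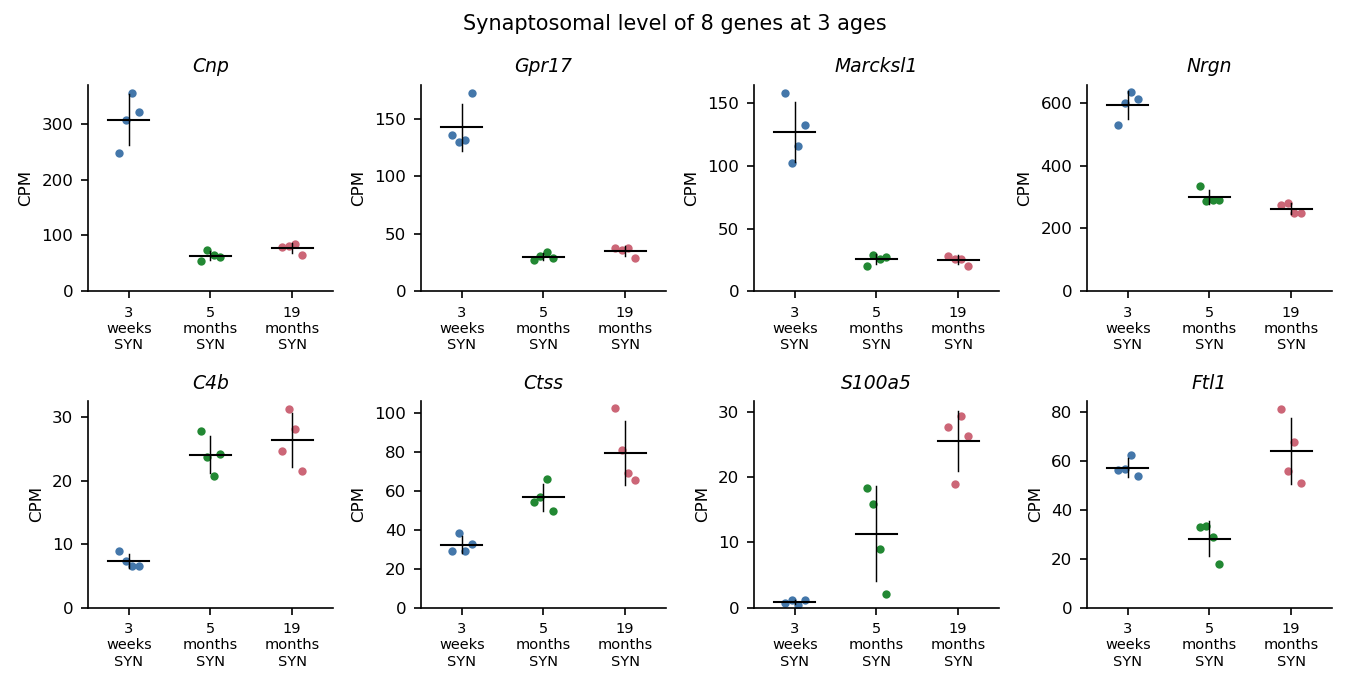
Levels of Cnp, Gpr17, Marcksl1, Nrgn, C4b, Ctss, S100a5 and Ftl1 in CPM, scaled over all 16 libraries, in the SYN libraries of 3 ages. Each point is 1 library, with the group mean as a line and the SD as a bar (n = 4 per age). Cnp, Gpr17, Marcksl1 and Nrgn were lower at both later ages than at 3 weeks, C4b, Ctss and S100a5 were higher, and Ftl1 was higher at 19 months than at 5 months.

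The comparison of 19 months with 5 months asks what differs between the synaptosomes of adult and aged mice. Few genes passed the test, 20 of 15344 higher and 26 lower at 19 months, together 0.3% of the genes, while 2103 had an unadjusted p under 0.05. Ftl1, the ferritin light chain that stores iron (ENSMUSG00000050708, chromosome 7, 45457944 to 45459884), stood at 54.7 ± 11.5 CPM at 19 months and 24.3 ± 6.12 CPM at 5 months (log2 fold change 1.17, SE 0.161, edgeR adjusted p = 0.00708). Microglial markers and cytosolic ribosomal protein genes were higher as lists, though 1 of 24 and 3 of 77 members passed the test and both list calls were lost with an estimated correlation (adjusted p = 0.508 and adjusted p = 0.385). C1qb, a chain of the complement component C1q made by microglia, stood at 28.2 ± 6.31 against 16.6 ± 3.19 CPM (log2 fold change 0.77, SE 0.158, edgeR adjusted p = 0.0279). Rbm25, a splicing factor, stood at 88.0 ± 7.21 against 138 ± 19.0 CPM (log2 fold change -0.64, SE 0.122, edgeR adjusted p = 0.0222).

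Of 24 microglial markers, 1 rose and 0 fell (9 and 0 adjusted over the list alone), with a median log2 fold change of 0.40 (camera adjusted p = 1.95e-06, adjusted p = 0.508 with an estimated correlation). Of 77 cytosolic ribosomal protein genes, 3 rose and 0 fell (7 and 0 adjusted over the list alone). The median was 0.25 (camera adjusted p = 3.55e-06, adjusted p = 0.385 with an estimated correlation). The 3 called members were Rpl32 (0.63), Rps9 (0.52) and Rps3a3 (0.70). Counts of Rps3a3 are uncertain because it is a near copy of another ribosomal protein gene. Without 5 months SYN replicate 4 the median of the list was 0.14 (adjusted p = 0.00119). The elongation factor Eef1a1 (0.46) and the translationally controlled Tpt1 (7.78 ± 1.57 against 2.80 ± 0.701 CPM, 1.47) also rose. Tmem35a, a chaperone of nicotinic receptors (1.08), the transcription regulator Lmo2 (0.80), the G protein regulator Rgs10 (0.66) and the amino acid transporter Slc38a2 (0.65) were the other genes named as highest. Interneuron markers had a median of 0.22, with 0 of 21 called (1 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.00106, adjusted p = 0.508 with an estimated correlation). Replication-dependent histone genes had a median of 0.28, with 0 of 32 called (0 and 0 adjusted over the list alone, camera adjusted p = 0.008, adjusted p = 0.369 with an estimated correlation), or 0.42 without 5 months SYN replicate 4. Glutamate receptor genes had a median of 0.10, with 0 of 30 called (3 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.0231, adjusted p = 0.908 with an estimated correlation). Nuclear genes of oxidative phosphorylation had a median of 0.08, with 0 of 85 called (3 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.0231, adjusted p = 0.827 with an estimated correlation).

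Neuronal transcription factor genes had a median log2 fold change of -0.13, with 0 of 25 called (6 lower and 0 higher adjusted over the list alone, camera adjusted p = 0.000133, adjusted p = 0.508 with an estimated correlation). Splicing factor genes had a median of -0.11, with Rbm25 the 1 member of 60 that fell (10 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.00392, adjusted p = 0.649 with an estimated correlation). Postsynaptic density genes had a median of -0.11, with 0 of 31 called (2 lower and 0 higher adjusted over the list alone, camera adjusted p = 0.00331, adjusted p = 0.774 with an estimated correlation). Dendritic mRNAs had a median of -0.15, with 1 of 21 higher and 0 lower (1 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.0231, adjusted p = 0.774 with an estimated correlation). Immediate early genes had a median of -0.21, with 0 of 27 called (2 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.0231, adjusted p = 0.827 with an estimated correlation). Presynaptic genes had a median of -0.07, with 0 of 33 called (3 lower and 0 higher adjusted over the list alone, camera adjusted p = 0.0306, adjusted p = 0.674 with an estimated correlation). The named genes that fell were the Mediator subunit Med6 (-0.91), the threonyl-tRNA synthetase Tarsl2 (-0.68), the zinc finger gene Zscan18 (-0.68), Fnbp4 (-0.62), the glial transcription factor Sox9 (-0.57), the splicing-associated Pnisr (-0.55) and Tnks1bp1 (-0.54). Snap25 (-0.22, edgeR adjusted p = 0.253), Camk2a (-0.21, 0.348), Dlg4 (-0.11, 0.62), Syn1 (-0.05, 0.856), Mbp (0.06, 0.862), Gfap (0.08, 0.725), C4b (0.12, 0.752), Malat1 (-0.72, 0.544) and mt-Co1 (-0.20, 0.837) did not pass the test. Without 5 months SYN replicate 4 Malat1 was at 0.08, and mt-Co1 ranged from -0.63 to -0.03 over the fits that leave 1 library out.

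The gene calls of this comparison depended on single libraries. Without 19 months SYN replicate 3 no gene was called by edgeR (1673 with an unadjusted p under 0.05), without 5 months SYN replicate 2 there were 60 higher and 64 lower, and 0 of the 46 genes were called in all 8 fits that leave 1 library out. Without 5 months SYN replicate 1 there were 2 higher and 0 lower, without its replicate 3 2 and 1, and without its replicate 4 2 and 2. Without 19 months SYN replicate 1 there were 4 higher and 5 lower, without its replicate 2 10 and 7, and without its replicate 4 3 and 1. DESeq2's Wald test called 106 higher and 200 lower, and edgeR on only the 8 compared libraries 132 and 188. Ftl1 lost its call only without 19 months SYN replicate 3 (1.14, edgeR adjusted p = 0.0518) and Tnks1bp1 without 5 months SYN replicate 1 (-0.50, 0.0664) or 19 months SYN replicate 3 (-0.54, 0.0536). Tpt1 lost it without 5 months SYN replicate 1 (0.0653), its replicate 4 (0.0586) or 19 months SYN replicate 3 (0.0536). Each other gene named as higher or lower lost its call in 5 to 7 of the 8 such fits, with its direction kept.

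Among the lists, microglia, ribosomal proteins, interneuron markers, transcription factors and histones kept their calls in all 8 of these fits. With an estimated correlation all 5 were lost (adjusted p = 0.508, 0.385, 0.508, 0.508 and 0.369). Postsynaptic density genes lost the call without 19 months SYN replicate 1 (-0.07, adjusted p = 0.0618) and splicing factors without 5 months SYN replicate 4 (-0.08, adjusted p = 0.0773). Presynaptic genes lost it with 5 months SYN replicate 1 or 3 or 19 months SYN replicate 1 or 2 left out (adjusted p = 0.0515 to 0.157), and dendritic mRNAs with 5 months SYN replicate 1, 2 or 3 or 19 months SYN replicate 1 left out (adjusted p = 0.0705 to 0.111). Glutamate receptors lost it with 5 months SYN replicate 1 or 4 or 19 months SYN replicate 2 or 3 left out (adjusted p = 0.113 to 0.27), with a median of 0.16 without 5 months SYN replicate 2 or 19 months SYN replicate 1 and 0.06 without 19 months SYN replicate 3. For immediate early genes this was so with 5 months SYN replicate 2 or 3 or 19 months SYN replicate 2 or 3 left out (adjusted p = 0.0551 to 0.103), and for oxidative phosphorylation with 5 months SYN replicate 3 or 4 or 19 months SYN replicate 1 left out (adjusted p = 0.0864 to 0.257), with a median of 0.15 without 5 months SYN replicate 1 and 0.05 without its replicate 4 or 19 months SYN replicate 1. Without 19 months SYN replicate 1 voltage-gated channels and synaptic adhesion genes (both 0.11, adjusted p = 0.00475), GABA receptors (0.0305) and perineuronal net genes (0.0487) were called as higher, and so were immune genes without 5 months SYN replicate 1 (0.28, adjusted p = 0.0431). With another library left out the largest adjusted p of these 5 lists ran from 0.342 to 0.792. The mitochondrially encoded mRNAs were not called (median -0.14, camera adjusted p = 0.0842). They were lower without 19 months SYN replicate 1, the library with the highest mitochondrial rRNA share (-0.60, adjusted p = 7.16e-07) or without 5 months SYN replicate 4 (-0.22, adjusted p = 0.0221). In the other fits with 1 library left out they were not called, with a median as high as 0.02 and adjusted p up to 0.52. Cell cycle genes, small nucleolar RNAs and proteasome genes, none of them called, had medians of -0.02, 0.05 and -0.00 and means of 0.09, -0.09 and 0.02, with an upward test direction in each.

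The comparison of 19 months with 3 weeks spans both intervals. As at 5 months, transcripts of myelin, of oligodendrocyte precursors and of growing axons were lower than at 3 weeks as lists, and microglial and immune genes were higher, as were 3 single genes of olfactory sensory neurons. With an estimated correlation the oligodendrocyte precursor call held (adjusted p = 0.0193), and those of myelin (adjusted p = 0.247), axon growth (0.063), microglia (0.239) and immune genes (0.114) did not. Marcksl1 stood at 21.4 ± 3.13 CPM at 19 months and 109 ± 20.5 CPM at 3 weeks (log2 fold change -2.34, SE 0.136, edgeR adjusted p = 4.26e-12). Ctss, a lysosomal protease of microglia, stood at 68.2 ± 14.1 against 27.6 ± 3.58 CPM (edgeR adjusted p = 3.77e-08). Omp, the marker protein of mature olfactory sensory neurons (ENSMUSG00000074006, chromosome 7, 98143359 to 98145502), stood at 14.3 ± 2.03 against 0.716 ± 0.383 CPM (log2 fold change 4.36, SE 0.372, edgeR adjusted p = 7.95e-08). Of 15344 genes tested, 1534 were higher and 1448 lower at 19 months, together 19.4% of the genes.

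Of 24 microglial markers, 12 rose and 0 fell (17 and 0 adjusted over the list alone), with a median log2 fold change of 0.72 (camera adjusted p = 4.82e-08, adjusted p = 0.239 with an estimated correlation), C1qb (1.11) and C1qa (0.99) among them. Of 27 immune genes, 10 rose and 1 fell (11 and 1 adjusted over the list alone). The median was 0.55 (camera adjusted p = 0.000328, adjusted p = 0.114 with an estimated correlation). C4b stood at 22.6 ± 3.63 against 6.26 ± 0.926 CPM (1.86) and Lyz2 at 2.01. Of 77 cytosolic ribosomal protein genes, 18 rose and 1 fell (21 and 3 adjusted over the list alone). The median was 0.31 (camera adjusted p = 0.000278, adjusted p = 0.239 with an estimated correlation), Rpl19 (1.31) and Rplp1 (157 ± 6.88 against 91.6 ± 24.6 CPM) among them. Of 44 voltage-gated channel genes, 17 rose and 3 fell (20 and 4 adjusted over the list alone). The median was 0.22 (camera adjusted p = 0.00189, adjusted p = 0.695 with an estimated correlation), and Hcn2 was at 0.88. Small nucleolar RNA genes had a median of 0.75, with 3 of 8 higher and 0 lower (3 and 0 adjusted over the list alone, camera adjusted p = 0.0055, adjusted p = 0.334 with an estimated correlation). Nuclear long noncoding RNAs had a median of 0.59, with 3 of 13 higher and 1 lower (4 and 1 adjusted over the list alone, camera adjusted p = 0.0133, adjusted p = 0.36 with an estimated correlation), a call lost without 19 months SYN replicate 1 (0.55, adjusted p = 0.0602). The genes with the highest log2 fold changes were S100a5 (4.88), Omp (4.36) and Stoml3 (4.27, or 5.56 without 3 weeks SYN replicate 2), all 3 of them known from olfactory sensory neurons. Of 9 tested members of a list of olfactory sensory neuron markers, drawn up after these 3 were seen, no other passed (median 0.72), with Cnga4 at 1.69, Ano2 at 0.72, Rtp1 at 0.54, Gng13 at 0.20, Adcy3 at 0.02 and Kirrel2 at -0.26. Gad1, the GABA-synthesizing enzyme, was at 0.70, and interneuron markers as a list were not called (4 higher and 0 lower, 4 and 0 adjusted over the list alone, camera adjusted p = 0.216). Gfap was at 0.29 (edgeR adjusted p = 0.0163) and lost its call without 3 weeks SYN replicate 4 (0.0605), 19 months SYN replicate 2 (0.0733) or its replicate 3 (0.0507).

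Of 29 myelin genes, 17 fell and 3 rose (17 and 3 adjusted over the list alone), with a median log2 fold change of -1.42 (camera adjusted p = 5.07e-10, adjusted p = 0.247 with an estimated correlation). Cnp (66.4 ± 7.23 against 263 ± 39.3 CPM, -1.98), Cldn11 (-2.49), Mog (-2.46) and Mbp (-1.64) were lower. Of 16 oligodendrocyte precursor markers, 10 fell and 0 rose (13 and 0 adjusted over the list alone). The median was -0.76 (camera adjusted p = 5.07e-10, and adjusted p = 0.0193 with an estimated correlation), Gpr17 (-2.02) and Enpp6 (-2.55) among them. Of 34 axon growth genes, 23 fell and 0 rose (23 and 0 adjusted over the list alone). The median was -0.67 (camera adjusted p = 1.87e-12, adjusted p = 0.063 with an estimated correlation), and the microtubule regulator Stmn2 was at -1.02. Of 20 cell cycle genes, 9 fell and 0 rose (10 and 0 adjusted over the list alone). The median was -0.82 (camera adjusted p = 2.93e-06, adjusted p = 0.063 with an estimated correlation), Mki67 at -2.43. Of 25 neuronal transcription factor genes, 13 fell and 0 rose (15 and 0 adjusted over the list alone). The median was -0.26 (camera adjusted p = 2.93e-06, adjusted p = 0.16 with an estimated correlation).

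Proteasome and chaperone genes had a median log2 fold change of -0.31, with 13 of 32 lower and 0 higher (13 and 0 adjusted over the list alone, camera adjusted p = 0.000111, adjusted p = 0.114 with an estimated correlation). Cholesterol synthesis genes had a median of -0.41, with 7 of 24 lower and 0 higher (9 and 0 adjusted over the list alone, camera adjusted p = 0.000366, adjusted p = 0.334 with an estimated correlation), Hmgcs1 at -1.32. Perineuronal net genes had a median of -0.61, with 6 of 10 lower and 2 higher (7 and 2 adjusted over the list alone, camera adjusted p = 0.00189, adjusted p = 0.239 with an estimated correlation). Collagens and basement membrane genes had a median of -0.26, with 6 of 26 lower and 0 higher (6 and 1 adjusted over the list alone, camera adjusted p = 0.0133, adjusted p = 0.306 with an estimated correlation). Presynaptic genes had a median of -0.07, with 13 of 33 lower and 3 higher (14 and 3 adjusted over the list alone, camera adjusted p = 0.0145, adjusted p = 0.334 with an estimated correlation). The SNARE protein gene Stx1a (-0.85) and Syn1 (-0.64) fell, and the list was not called without 19 months SYN replicate 1 (-0.01, adjusted p = 0.0619). The presynaptic median was -0.17 without 3 weeks SYN replicate 1, 0.00 without its replicate 4, and -0.14 and -0.13 without 19 months SYN replicates 2 and 3. Postsynaptic density genes were not called (median 0.14, 9 higher and 7 lower, 12 and 7 adjusted over the list alone, camera adjusted p = 0.239), though Nrgn stood at 225 ± 14.5 against 506 ± 39.9 CPM (-1.17). Camk2a (0.13, edgeR adjusted p = 0.42), Snap25 (0.08, 0.608), Dlg4 (-0.13, 0.34) and Malat1 (1109 ± 238 against 491 ± 61.5 CPM, 0.125) did not pass the test. The mitochondrially encoded mRNAs were not called (median -0.35, camera adjusted p = 0.0687). They were lower without 19 months SYN replicate 1 (-0.79, adjusted p = 2.89e-05) or 3 weeks SYN replicate 4 (-0.47, adjusted p = 0.0178), but not in the other fits with 1 library left out (adjusted p up to 0.216). Without the first of these libraries mt-Co1 moved from -0.39 (edgeR adjusted p = 0.446) to -0.82 (0.000565).

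Against 3 weeks, 6 lists were higher and 10 lower at 19 months, and only the oligodendrocyte precursor call held with an estimated correlation. Without 3 weeks SYN replicate 1 dendritic mRNAs (adjusted p = 0.0361) and clock genes (0.0357) were also called as higher and adhesion genes as lower (0.0122). Without 3 weeks SYN replicate 4 immediate early genes were higher (0.00988) and splicing factors lower (0.0438), and without 19 months SYN replicate 1 glutamate receptors were higher (0.0487) and oxidative phosphorylation genes lower (0.042). With another library left out the largest adjusted p of these 7 lists ran from 0.215 to 0.982. The uncalled meninges list had a median of 0.09 and a mean of -0.20 with a downward test direction, and the uncalled immediate early genes a median of -0.03 and a mean of 0.13 with an upward one.

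The age comparisons share libraries, so overlaps were set beside reference values. Of the genes higher at 5 months than at 3 weeks, 1137 were also higher at 19 months than at 3 weeks, and 997 were lower in both. Independent lists of those sizes would share 203 and 164 genes. Simulated unchanged groups shared 0 and 0, but with no true change to call they give no chance value for such lists. With the 3 weeks libraries split between the comparisons, so fewer in each, the mean overlaps were 504 and 546 genes. Across genes, which are not independent replicates, log2 fold changes had a covariance of 0.297 (0.0379 simulated, 0.38 split). The correlation was 0.82 (0.493 simulated, 0.611 split). Between 5 months against 3 weeks and 19 months against 5 months, 17 genes were first higher and then lower and 8 first lower and then higher, where independent lists would share 3.45 and 2.27. Just 1 gene was higher and 1 lower in both. With the 5 months libraries split, the mean number of genes that changed in opposite directions was 6.5, and 4.17 were higher and 0.5 lower in both. The covariance was -0.0922 against -0.0385 simulated, and -0.0167 with the 5 months libraries split, but the correlation of -0.406 was weaker than the simulated -0.499 (-0.0375 split). Between 19 months against 5 months and against 3 weeks, 12 genes were higher and 8 lower in both, where independent lists would share 2 and 2.45. With the 19 months libraries split these overlaps were 0, the covariance of 0.0401 lay next to the simulated 0.0395, and the correlation was 0.19 against 0.508 simulated.

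Splicing in synaptosomes was compared between ages with the authors' deposited tables, which answer whether transcripts change their isoforms with age. LeafCutter groups introns that share splice sites into clusters and tests the usage of each intron within its cluster. Between 3 weeks and 5 months the authors' deposited table held 4250 tested clusters, of which 281 (6.61%) had an adjusted p under 0.05, in 284 named genes, since a protocadherin gamma cluster carries many gene names. Among them, 195 had a change in usage of at least 0.1 for 1 intron, and 105 had the 3 introns of an exon that is included or skipped. Between 5 months and 19 months 31 of 4037 clusters (0.768%) were called, and between 3 weeks and 19 months 201 of 4176 (4.81%). The deposited values are 1 fitted usage per age and carry no replicate error.

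The genes named first are those with the smallest adjusted p between 3 weeks and 5 months in the authors' deposited table. For Mbp, the intron at chromosome 18, 82554751 to 82572824, which skips a coding exon of 78 bases (82561778 to 82561855), rose from 58.5% to 82.4% of its cluster (adjusted p = 1.91e-08, authors' deposited table). In the authors' deposited table the Mag intron at chromosome 7, 30899699 to 30900637, which skips an annotated exon of 45 bases (30900352 to 30900396), decreased from 70.2% to 17.1% (adjusted p = 3.05e-06). For Nfasc, an adhesion molecule of the axon initial segment and node, the intron at chromosome 1, 132621624 to 132631684, which skips a coding exon of 51 bases (132627872 to 132627922), went from 41.2% to 97.2% (adjusted p = 2.19e-08, authors' deposited table). Rims1, the active zone scaffold, had the smallest adjusted p of the authors' deposited table (4.47e-12), with the intron at chromosome 1, 22379541 to 22397450, at 50.7% and then 37.2%. In Bcas1, a gene of early myelinating oligodendrocytes, the intron at chromosome 2, 170349464 to 170378722, went from 7.49% to 32.6% (adjusted p = 1.91e-08, authors' deposited table). Of the synaptic genes chosen before the data were examined, the authors' deposited table called Map2 (64.8% to 83.2% for an intron skipping a coding exon of 93 bases, adjusted p = 0.00933), the NMDA receptor subunit Grin1 (72.7% to 57.2%, 63 bases, 0.0123) and Dnm1 (44.4% to 35.8%, 0.0481).

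Between 5 months and 19 months the smallest adjusted p of the authors' deposited table (0.00776) belonged to a cluster on the mitochondrial genome with no gene name, at 1219 to 1487, where usage went from 5.89% to 11.8%. The named genes of the authors' deposited table were led by the transcription factor Mef2a, in which the intron at chromosome 7, 67240441 to 67251656, skipping a coding exon of 24 bases (67244521 to 67244544), went from 1.04% to 19.9% (adjusted p = 0.0145). Ccp110, a centriolar protein gene, went from 46.9% to 10.1% for an intron skipping a coding exon of 86 bases (adjusted p = 0.0185, authors' deposited table). Clathrin light chain B, Cltb, went from 16% to 25.9% for the intron at chromosome 13, 54594043 to 54598721, which skips a coding exon of 54 bases (54597026 to 54597079) (adjusted p = 0.0185, authors' deposited table). Sh3glb1 (67.0% to 96.1%), Unc79 (58.5% to 37.9%), Dhx30 (8.03% to 22.1%), Ube2w (100% to 93.9%) and Ppfia2 (55.3% to 31%) completed the named genes of this authors' deposited table.

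Between 3 weeks and 19 months, in the authors' deposited table, the same introns of Bcas1 (7.90% to 24.8%, adjusted p = 3.21e-14), Rims1 (50.7% to 33.9%, 2.08e-13), Mbp (58.4% to 83.7%), Nfasc (41.3% to 77.8%) and Mag (70.3% to 17.2%, 6.89e-06) were called as at 5 months. Of the synaptic genes chosen beforehand it called Cltb (14.4% to 25.9%, adjusted p = 0.000473), Dnm1 (44.4% to 34%, 0.00197), Nrxn3 (27.2% to 11.3% for an intron skipping a coding exon of 90 bases, 0.0398), Mapt (62.3% to 68.9%, 0.0153), Camk2a (95.4% to 93.8%, 33 bases, 0.00664) and Camk2b (3.65% to 6.11%, 45 bases, 0.0407), all from the authors' deposited table. Of the clusters in the authors' deposited tables, 71 were called between 3 weeks and both later ages, where independent lists would share 13. The leading intron of all 71 changed in the same direction. Between the successive intervals 8 were shared against 1.96 for independent lists, but in 0 of the 8 did the leading intron change in the same direction. These pairs of tables share libraries, and part of each excess may come from them. The fixed gene lists were tested among LeafCutter genes in 52 exact tests, with a smallest adjusted p of 0.0796 by Fisher's exact test.

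**Figure D4:**
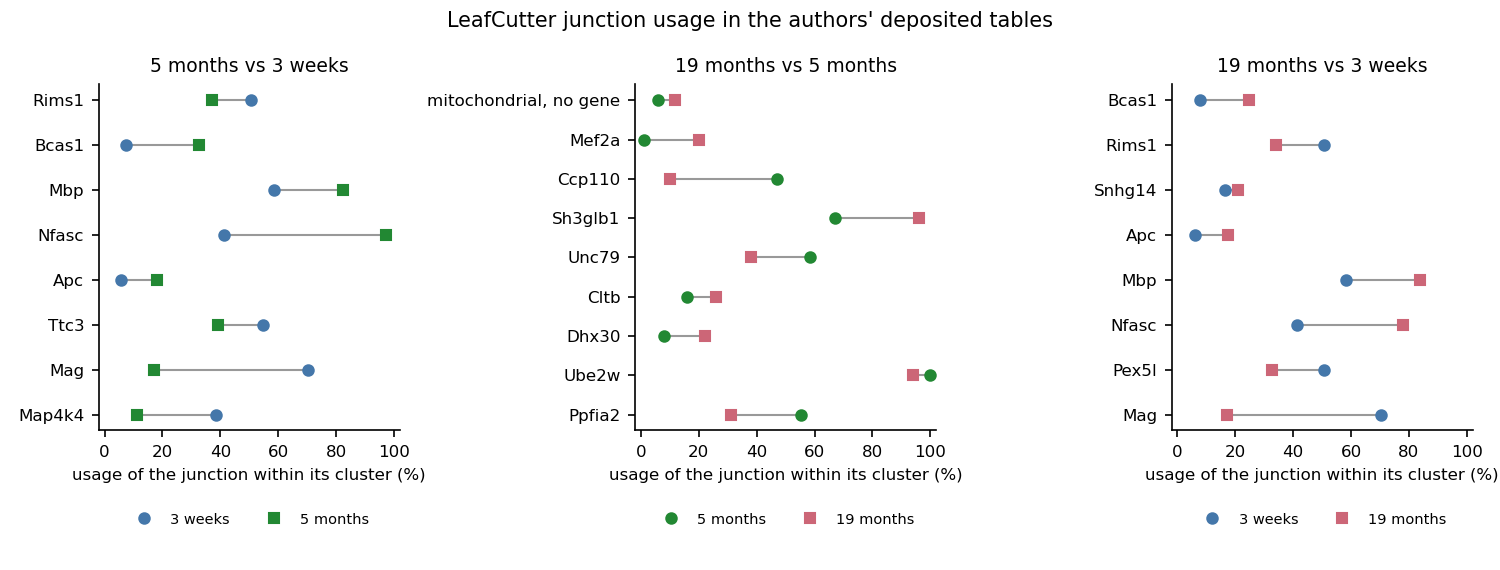
Usage of the leading junction of each named cluster in the authors' deposited LeafCutter tables, in percent of its cluster, for the 3 pairs of ages. Circles give the earlier and squares the later age, with 1 fitted value per age and no replicate error. The Mbp junction that skips a 78-base exon goes from 58.5% to 82.4% between 3 weeks and 5 months, and the Nfasc junction from 41.2% to 97.2%.

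DIEGO, which tests the share of each junction among the junctions of its gene, called 1399 junctions in 1097 genes at a q under 0.05 between 3 weeks and 5 months in the authors' deposited table. Between 3 weeks and 19 months the authors' deposited table gave 640 junctions in 527 genes, and between 5 months and 19 months 0 junctions (smallest q 0.0700, 1144 junctions with p under 0.05), where LeafCutter called 31 clusters. The table's own column for significance marked 0 junctions in each comparison. The smallest deposited p was 0.0209 in each table, below the 0.0286 that an exact rank-sum test of 4 against 4 can give, and with that exact value in its place no junction would be called (smallest q 0.0634, 0.0839 and 0.0668). Of genes that LeafCutter tested and the DIEGO table listed between 3 weeks and 5 months, 88 were called by both in the authors' deposited tables, against 38.7 for independent lists (odds ratio 3.63, 95% interval 2.71 to 4.85, Fisher's exact p = 1.85e-16). Between 3 weeks and 19 months 56 were called by both against 14.4 (odds ratio 6.98, 95% interval 4.86 to 10.0, Fisher's exact p = 8.35e-22). Both tools read the same libraries, so this overlap is not independent evidence. Here and below, names of the protocadherin gamma cluster count as genes but are not independent. LeafCutter genes called by edgeR numbered 119 against 98.8 for independent lists between 3 weeks and 5 months (odds ratio 1.42, 95% interval 1.10 to 1.83, Fisher's exact p = 0.00748, and 1.29 within quintiles of expression). Between 3 weeks and 19 months the number was 77 against 58.0 (odds ratio 1.61, 95% interval 1.19 to 2.17, Fisher's exact p = 0.00247, and 1.48 within quintiles). Between 5 months and 19 months 0 of 28 passed the expression test, against 0.217 (Fisher's exact p = 1).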

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

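The tests of carry-over and of a swapped label for 5 months SYN replicate 4 and the depth test for olfactory genes were chosen after the result was seen. The others were chosen after their pattern was seen, but before their values were. The 95% intervals below redraw genes, not libraries.

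In 5 months SYN replicate 4 nuclear and vascular transcripts lay toward TH. Carry-over of homogenate is a candidate explanation, since the median fraction of the way from the other 5 months SYN libraries to TH was 0.2051 (95% interval 0.1886 to 0.2206) over 453 genes, 0.2287 (0.2024 to 0.2605) for nuclear long noncoding RNAs and 0.1735 (0.0581 to 0.2149) for endothelial markers. A swapped label is argued against by a correlation difference of 0.0267 in favour of SYN. No biological explanation could be tested with this design, and the matter stays open.

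Ribosomal protein genes were higher at 19 than at 5 months by a median of 0.2519. A gene length bias is argued against by a percentile of 100 among 10000 lists matched for length and expression. A GC content bias is too, by 100 among those matched for it and expression. Reads moving between these genes and their pseudogenes cannot be told from other explanations by the pseudogene median of -0.0149 (-0.0607 to 0.0549). Without 5 months SYN replicate 4 the median of the list was 0.1426 (0.0213 to 0.2651). Pseudogene reads, that library and age all stay open.

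Omp, S100a5 and Stoml3 were higher at 19 months than at 3 weeks, while the other 6 of 9 tested olfactory sensory neuron markers were not called (median of the 9, 0.72, values above). Inclusion of olfactory bulb tissue is a candidate explanation, as bulb neuron markers had a median of 1.5356 (1.1402 to 1.8083, 6 of 9 tested), though at 5 months just Barhl2 of these 6 passed. Lower depth at 3 weeks is argued against by counts outside the mitochondrial genome that were 1.28 times those at 19 months. Age itself was not tested and stays open.

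Chance was tested with the 35 ways to part the 8 compared libraries into 4 and 4. The real grouping called 3773 genes in 5 months against 3 weeks (highest other 6) and 2982 in 19 months against 3 weeks (21). In 19 months against 5 months it called 46 (3), which depended on single libraries. A share of 1 in 35 makes chance unlikely but does not exclude it. In SYN against TH 8 groupings, the real one included, part all 4 pairs, too few for a share under 0.05. The real one called 8704 genes and each other grouping 0.

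In 300 groups of 4 libraries, 30 had a library far from the other 3 (about 1 in 20 by chance). Values follow with the range of the other 3. In 5 months SYN replicate 4 these were Malat1 4817 CPM (947.3 to 1458), Meg3 1306 (317.1 to 433.7), Kcnq1ot1 98.85 (7.628 to 19.74), Ptprb 9.682 (1.468 to 2.169) and Eif2s3y 9.368 (3.524 to 3.888). In 19 months SYN replicate 1 the mitochondrial rRNA share was 52.28% (32.88 to 33.61), mt-Co1 24810 CPM (9550 to 10800), Xist 5.922 (0.09398 to 0.633) and Ddx3y, which that share dilutes, 17.25 (25.34 to 26.97). In 5 months TH replicate 4 the mitochondrial mRNA share was 3.062% (2.571 to 2.638), mt-Co1 6214 CPM (4970 to 5177), mt-Nd1 2163 (1597 to 1686) and Kcnq1ot1 438.9 (356.8 to 367.5). In 3 weeks SYN replicate 1 Cldn11 was 76.67 CPM (155.5 to 159), Prom1 7.83 (12.68 to 13.11) and Top2a 8.238 (5.051 to 5.426). In 5 months SYN replicate 1 the mitochondrial mRNA share was 5.143% (4.008 to 4.179), Cldn11 13.26 CPM (18.23 to 18.84) and Nrgn 335.5 (288.8 to 290.8). In 3 weeks SYN replicate 3 Mbp was 3373 CPM (2398 to 2536) and Lin28b 2.1 (3.53 to 3.59), and in its replicate 4 Gpr17 was 172.8 (129.7 to 136.3) and Snora21 3.519 (0.6525 to 1.078). In 19 months SYN replicate 4 Gad1 was 134 CPM (117.1 to 118.2) and Gpr17 29.01 (36.18 to 37.53), and in its replicate 2 the counts outside the mitochondrial genome were 9.02 M (6.56 to 6.83). Single values were Xist 0.9795 CPM in 5 months SYN replicate 2 (0.3513 to 0.4187), Tnc 4.486 in 5 months SYN replicate 3 (3.453 to 3.589), Xist 0.1251 in 5 months TH replicate 3 (0) and Snap25 1391 in 5 months TH replicate 1 (1317 to 1324).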

How the results depend on the processing

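Leaving out both libraries that stand apart and the exact rank-sum p for DIEGO were chosen after the result was seen, and the other settings before.

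With a fold of at least 2, SYN against TH had 1353 genes higher and 2658 lower, 5 months against 3 weeks 491 and 302, 19 months against 5 months 5 and 0, and 19 months against 3 weeks 405 and 195. With an estimated correlation 0 lists were higher and 0 lower in SYN against TH, 0 and 1 in 5 months against 3 weeks, 0 and 0 in 19 months against 5 months, and 0 and 1 in 19 months against 3 weeks.

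Counts of 19 months against 5 months, 20 higher and 26 lower, moved most. They were 142 and 150 with no filter on low counts, 132 and 188 with only the 8 libraries compared, 106 and 200 with the DESeq2 Wald test, 14 and 14 with all 16 libraries, and 2 and 3 without both libraries that stand apart. With 1 library left out, as given above, they ran from 0 to 60 higher and from 0 to 64 lower. Lists called lower ran from 3 (without 5 months SYN replicate 3) to 6 (without 5 months SYN replicate 4). With a block by replicate number, for which not every sample correlates best with its own number, 124 genes were higher and 140 lower. With it the mitochondrially encoded genes were called lower in 19 months against 5 months (-0.21, adjusted p = 0.011) and 19 months against 3 weeks (-0.44, 0.0121), endothelial markers higher in 5 months against 3 weeks (0.24, 0.048), and presynaptic genes were not called in 19 months against 5 months (0.0551).

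In SYN against TH the block for the shared preparations gave 4152 genes higher and 4402 lower, and among the lists changed just the cholesterol biosynthesis call (adjusted p = 0.0519).

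At an adjusted p under 0.01 the LeafCutter tables held 85, 1 and 50 clusters for 5 months against 3 weeks, 19 months against 5 months and 19 months against 3 weeks. DIEGO held 0 genes in 5 months against 3 weeks and 0 in 19 months against 3 weeks at a q under 0.01, and 0 and 0 with the smallest p set to the exact rank-sum p.

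Without both libraries that stand apart some list calls ended. In 5 months against 3 weeks these were transcription factors (adjusted p = 0.086), circadian clock genes (0.0542) and small nucleolar RNAs (0.0548), in 19 months against 5 months presynaptic genes (0.052) and oxidative phosphorylation (0.824), and in 19 months against 3 weeks presynaptic genes (0.0843). The mitochondrially encoded genes became lower in 19 months against 5 months (-0.69, adjusted p = 2.73e-08) and 19 months against 3 weeks (-0.79, 4.02e-05), as did oxidative phosphorylation in the latter (0.0315).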

Other observations

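The bulb neuron markers were chosen after Omp, S100a5 and Stoml3 were seen, but before the values of the markers were.

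Markers of olfactory bulb neurons were higher at 19 months than at 3 weeks. By edgeR, Doc2g (log2 fold change 2.06, adjusted p = 0.0129), tyrosine hydroxylase Th (1.55, 0.0102), Sp8 (1.38, 0.000623) and Barhl2 (1.55, 0.0203) passed, and Eomes (1.52, 0.21) and Trh (0.90, 0.0522) did not. Omp lay at 0.227 to 1.22 CPM in the 3 weeks SYN libraries, 3.88 to 12.5 in 5 months SYN, 13.6 to 19.3 in 19 months SYN and 1.89 to 3.13 in 5 months TH. Replicate 4 was lowest in both 5 months fractions for Cdhr1 (6.1 against 24.3 to 48.5 CPM in SYN, 4.78 against 11.8 to 21.6 in TH) and S100a5 (2.09 against 8.97 to 18.3, 0.996 against 2.34 to 5.58). Stoml3 was lowest there in SYN (2.87 against 10.2 to 13.3) but highest in TH (3.45 against 0.999 to 2.2).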
